A study of Rattus norvegicus with 59 samples.

How the data were processed

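RNA was taken from a piece of lung of 59 male Fischer F344 rats, 1 library per rat, per the labels' protocols. Total RNA was isolated with miRNeasy kits including DNase treatment, and libraries were made with the TruSeq Stranded Total RNA kit with Ribo-Zero Gold depletion of ribosomal RNA, per the labels' protocols. The tools named per the submitters' processing notes, with no role or order given, were bcl2fastq 2.19, Trimmomatic 0.35, TopHat2 2.0.9, Bowtie2 2.2.9 and Cufflinks 2.1.1. The genome build and the annotation were not given in the sources used here. The values deposited by the authors were FPKM, fragment numbers divided by transcript length and by the mapped total of the library, per the title the authors gave the deposited table, with 1 column per library and 1 line per gene name. Each column was matched to a sample by its name, and 0 columns of values were left unmatched.

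The table held 2888 gene entries. The last was incomplete, with 31 of its 59 values, and was left out. A RefSeq gene table of the rat assembly GRCr8 was used only for names and for the order of neighbouring genes, since the build behind the FPKM was not named, and no coordinates were taken from it. It held 1729 of the names as symbols and 332 as synonyms, 2061 in all, and 2046 of them lay on chromosome 1. The table therefore covers part of the genome, and genes elsewhere were not analysed here. As it ends within an entry, it can be the first part of a longer table, and FPKM sums and shares refer to the entries present. The genes not analysed include Lcn2, Spp1, Mmp12, Ccl2, Cxcl1, Col1a1, Col3a1, Sftpc, Hmox1 and Cxcl13, which were to be given whatever their values.

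FPKM are not counts, so no count model was used. Genes with an FPKM of at least 1 in at least 4 libraries were tested, 1278 of 2887 (44.3%), and 1609 were not. Tests were run with limma 3.58.1 in R 4.3.3 on log2(FPKM + 0.5), with an intensity trend in the empirical Bayes step, and p was adjusted by the Benjamini-Hochberg method over all tested genes within a comparison, with a threshold of 0.05. All 12 groups entered one fit, with 47 residual degrees of freedom and a prior of 3.41, and no covariate, as the labels give no batch. A fold change is on the log2(FPKM + 0.5) scale and understates the change of low genes. The comparisons were silica against air at each of the 6 times, the mean of the 6 differences, an F test of whether the difference varied between times, the difference at 18 months against that at 1 month, and air at 18 months against air at 1 month. Each time had its own air group, so no control libraries were shared between times. Python 3.11.15 with matplotlib 3.10.9 drew the plots.

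Named genes were chosen by a rule set before the data were examined, among called genes with a gene symbol and a mean FPKM of at least 1. The mean over times names the 12 largest rises and 8 largest falls. Each time names up to 6 rises and 4 falls among genes whose silica and air values do not overlap, air at 18 months against 1 month names 6 rises and 4 falls, and the remaining comparisons name the 10 smallest p.

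Gene lists were tested with limma's camera at a preset correlation of 0.01 and adjusted over all lists within a comparison, for lists with at least 3 tested genes. Of 42 lists fixed before the data were examined, 2 reached that number (B cell markers, and erythrocyte and blood content), 23 had 1 or 2 tested genes and 17 had none. A further 19 lists were written from the gene symbols of the table after it was seen and before any comparison of groups, which makes 21. Called members are given from the adjustment over all tested genes, and for fixed lists also adjusted over the list alone. Of the 38 distinct tested genes on fixed lists, 11, 12, 18, 19, 15 and 17 were called from the 1-month to the 18-month comparison, 0 in the comparison of 18 months with 1 month and 11 with age in air. Among all tested genes 8.84%, 18.2%, 27.6%, 30.8%, 23.6% and 15.3% were called from 1 to 18 months. The share was 57.6% in the mean over times, 0.156% for 18 months against 1 month and 21.8% with age in air. Counts of called list genes are to be read against these shares. Camera was repeated with a correlation estimated per list, and the rotation test fry and an exact permutation test of the list mean per library were run beside it.

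Depth is not given directly by FPKM. In 261 entries above 0 in 3 to 15 libraries, values of a gene fell on steps: of 1997 values, 63.7% lay within log2 0.1 of 1 step, 8.81% of 2 steps and 1.50% of 3 steps after scaling each library. The step sizes gave each library a relative depth, 0.431 to 2.26, without giving whole reads for most genes. With 4 or 5 rats per group the median SE of a log2 change at 1 month was 0.0994. No 2 libraries of a group were identical. The titles give each library a number of its own, and the labels describe the groups as groups of rats, so p-values measure the spread between rats.

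The fit was tested on simulated data made from each gene's mean over the groups and its spread within groups, with genes drawn independently. At 6 months, with 200 of 1278 genes changed, 88% of genes changed by log2 0.5 were recovered, 100% at log2 1, 98% at log2 1.5 and 96% at log2 2, with 50 genes at each size, and 10 of 201 calls were false (4.98%). At 12 months, with no gene changed, 0 genes were called and 5.16% had an unadjusted p under 0.05. A list moved by log2 0.4 was called and 0 of 20 unmoved lists were. As the simulated genes were independent, this cannot test the preset correlation on which list calls in the real data rest. Every simulated group also had the same spread for a gene. The simulation therefore cannot show false calls where 1 group varies more than the others. In the real data the calls at 12 months fell from 302 to 1 when the 12-month groups were fitted alone.

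Alternatives set before the data were examined were pseudocounts of 0.1 and 1, no filter beyond a value above 0, a mean FPKM of at least 5, centring on library medians, quantile normalization, a robust variance prior, array weights, a limit of log2 1 on the change, a fit of the 2 groups of a time alone, each time left out and each replicate left out. Chosen after seeing the data were fits without replicate 3 of the 12-month silica group in comparisons other than that of 12 months, and without the 2 libraries in which LOC102553223 took over 50% of the FPKM present. The calls of each comparison were also counted under 100 splits of the same libraries, the real one included.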

Results

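The lungs of male Fischer F344 rats were examined after whole-body inhalation of crystalline silica, the mineral dust that causes silicosis, or of air. The exposed rats breathed 15 mg/m3 for 6 h per day on 5 days and were 3 months old at purchase. RNA from a piece of lung was sequenced at 6 times after exposure, at months 1, 3, 6, 9, 12 and 18, with 5 rats in each of the silica and air groups at every time except the 9-month air group, which held 4. Each of the 59 libraries came from 1 rat. The comparisons ask how silica lungs differed from air lungs of the same time, whether that difference changed with time, and what changed in air lungs with age.

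The table analysed covered part of the genome. It held 2887 complete gene entries in FPKM, of which 2061 carried a symbol known to the rat annotation used for names, and 2046 of these (99.3%) lay on chromosome 1. Of the complete entries, 1278 reached an FPKM of 1 in at least 4 libraries and were tested, 274 of them with placeholder or small RNA names. It ends within an entry and can therefore be the first part of a longer table, so sums and shares of FPKM refer to the entries present. Genes elsewhere in the genome were not analysed here. The FPKM of a library summed to between 12818 and 38613, and without the entry LOC102553223, which took up to 25818 FPKM, to between 12025 and 16336. Relative depth, read from the steps of low FPKM values, ranged 5.24-fold between libraries, from 0.431 to 2.26 of the typical library. It did not separate silica from air at any time (exact two-sided permutation p = 0.119 to 0.746, n = 5 and 5, or 5 and 4 at 9 months). Within groups, log2 values of library pairs correlated across genes at r = 0.912 to 0.983 over 116 pairs, none identical.

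Across the 6 times Cd177, a surface glycoprotein of neutrophils, rose 3.99-fold, a log2 change of 1.996 ± 0.093 (SE; limma adjusted p = 2.43e-24, 30 silica and 29 air libraries). Lilrb4, an inhibitory receptor of myeloid cells, rose by 1.12 ± 0.078, the integrin alpha M gene Itgam by 0.93 ± 0.084, and Plaur, the urokinase receptor, by 0.93 ± 0.070. Sod2, the mitochondrial superoxide dismutase, rose 2.03-fold (1.02 ± 0.063), and Arg1, arginase, 1.92-fold (0.94 ± 0.075). Esr1, which encodes estrogen receptor alpha, rose by 1.47 ± 0.11 on average, with large differences between times given further on. The other genes with the largest rises were Ceacam10 (1.21 ± 0.084), Enpp3, an ectonucleotide pyrophosphatase (1.00 ± 0.066), Meis3 (0.95 ± 0.089), Tmem86a (0.91 ± 0.088) and P2ry2, a purinergic receptor (0.90 ± 0.063), with adjusted p between 2.43e-24 and 1.05e-12 for the 12. Values of some placeholder entries followed Cd177 or Ceacam10 closely, LOC100909700 at 1.98, LOC103691058 at 1.95 and LOC103689942 at 1.19, so reads shared between copies can leave their levels uncertain. Lilrb4 has a second entry, Lilrb4-2, whose values did not follow it over libraries (Pearson r = -0.175).

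Falls across the 6 times were smaller. Dll1, a ligand of Notch receptors, fell by 0.48 ± 0.088 on the log2 scale (SE; limma adjusted p = 7.70e-06), Acsm5, an acyl-CoA synthetase, by 0.46 ± 0.054, the amino acid transporter gene Slc7a10 by 0.43 ± 0.058, and Fxyd1, a regulator of the sodium pump, by 0.42 ± 0.063. Akap12, a scaffold of protein kinase A, fell by 0.42 ± 0.051. Cox8b, the heart and skeletal muscle form of a cytochrome oxidase subunit, changed by -0.49 ± 0.18 (adjusted p = 0.0180), and its adjusted p was 0.0523 without the 9-month groups and 0.0636 without the 18-month groups. The beta-globin genes Hbb and Hbb-b1 fell by 0.41 ± 0.078 and 0.42 ± 0.086, but Hbb changed by 0.062 after quantile normalization (adjusted p = 0.681), and entries of this globin cluster can share reads.

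Among gene lists, 16 of 19 myeloid receptor genes and 13 of 16 lysosome genes rose in the mean over times and none fell. Examples were Oscar (0.66 ± 0.052) and C5ar1, the receptor of complement C5a (0.74 ± 0.059), in the first, and the peptidase gene Tpp1 (0.35 ± 0.028) and Prcp (0.61 ± 0.051) in the second. Both lists ranked above the other genes (camera adjusted p = 1.64e-05 and 7.01e-06; adjusted p = 0.261 for both with an estimated correlation). Of 6 genes related to alveolar type 2 cells, 5 rose, among them Lpcat1, an enzyme of surfactant lipid synthesis (0.67 ± 0.042), the protease gene Napsa (0.64 ± 0.047) and the transcription factor gene Cebpa (0.47 ± 0.043; camera adjusted p = 0.00396, 0.261 with an estimated correlation). All 10 endothelial genes fell (median -0.24; camera adjusted p = 2.13e-05, 0.261 with an estimated correlation), including Ehd2, a protein of caveolae (-0.25 ± 0.027), and Rasip1 (-0.33 ± 0.046).

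Of the cell cycle list, 11 of 14 genes rose, with the proliferation marker Mki67 at 0.72 ± 0.054 and Prc1 at 0.67 ± 0.057 (SE; camera adjusted p = 0.0123). Oxidant, haem and iron genes rose in 11 of 15 and fell in 2 (adjusted p = 0.00737), with the ferritin light chain gene Ftl1 at 0.74 ± 0.067. Airway and surface epithelium genes rose in 11 of 19 and fell in 1 (adjusted p = 0.0123), with Cxcl17, a mucosal chemokine, at 0.65 ± 0.043 and the protease inhibitor gene Spint2 at 0.37 ± 0.028. Cilia genes fell in 11 of 20 (adjusted p = 0.00338), zinc finger genes fell in 19 and rose in 4 of 48 (adjusted p = 0.00266), and matrix genes fell in 14 and rose in 7 of 27 (adjusted p = 0.0279). In the matrix list the smallest p belonged to Cpxm2 at 0.58, Furin, a protease that processes precursors, at 0.29, the receptor gene Axl at 0.25 and Tgfb1 at 0.36. Mitochondrial genes rose in 14 of 24 (adjusted p = 0.0410) and cytochrome P450 and conjugation genes fell in 3 of 11 (adjusted p = 0.0314). With an estimated correlation these 8 lists had adjusted p = 0.261 to 0.444. After median centring the matrix, mitochondrial and cytochrome P450 lists missed the threshold (adjusted p = 0.0613 to 0.106).

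The erythrocyte list, fixed before the data were examined, fell in 2 of 3 genes in the mean over times, also 2 adjusted over the list alone (camera adjusted p = 0.0467, 0.270 with an estimated correlation, 0.0618 without replicate 3 of the 12-month silica group, and 0.118 after median centring). B cell markers, the other fixed list that could be tested, fell in 1 of 3 genes, 1 adjusted over the list alone, and the list missed the threshold (adjusted p = 0.185). Of the 38 tested genes that stood on any fixed list, 25 were called in the mean over times, where 57.6% of all tested genes were called. Leukocyte integrin (8 of 12 genes higher and 3 lower, adjusted p = 0.0784), lymphocyte (adjusted p = 0.209), apolipoprotein and lipid (0.0599), NF-kB and TNF (0.271), interferon (0.732), ribosomal protein (0.525) and striated muscle lists (0.267) did not pass in the mean over times.

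**Figure D1:**
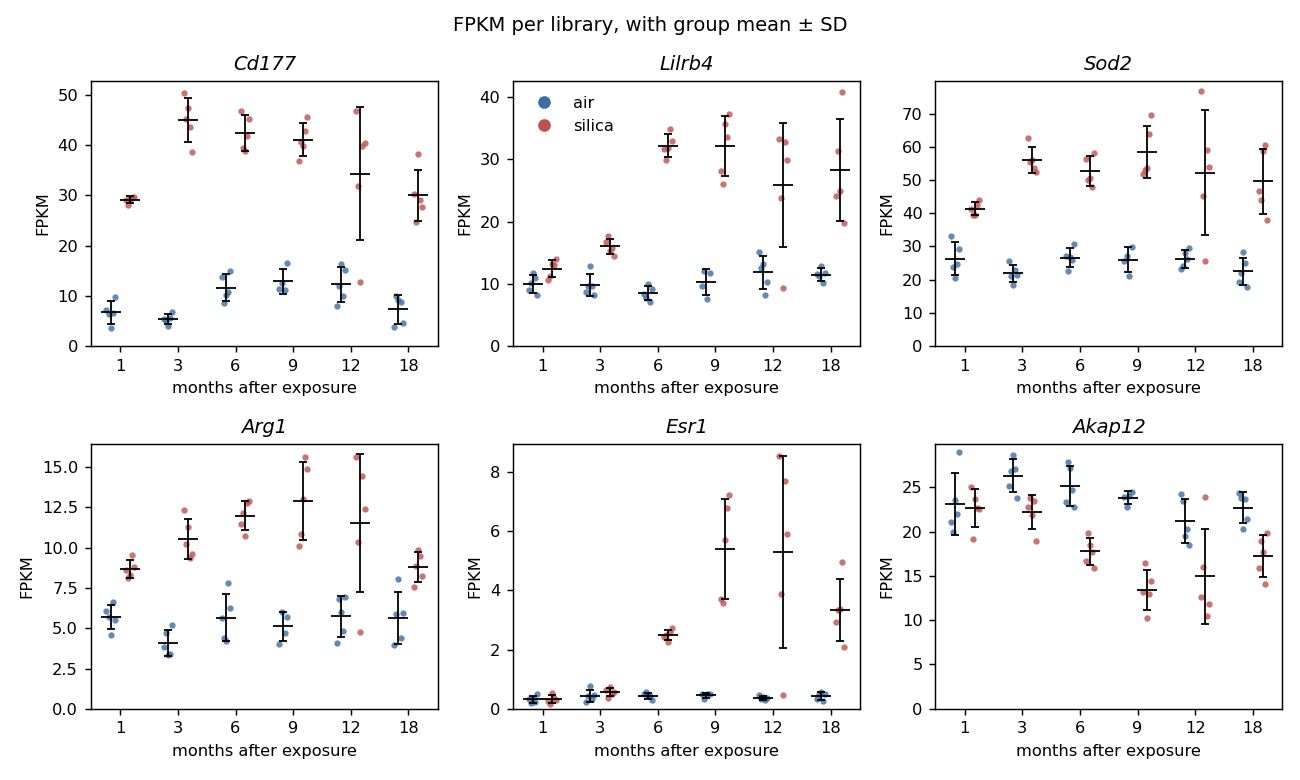
FPKM of 6 named genes (vertical axes) against months after exposure, with 1 point per library, air in blue and silica in red, and bars for the group mean ± SD (n = 5, air at 9 months n = 4). Esr1 stays below 1 FPKM in both groups at 1 and 3 months and averages 2.50 to 5.40 FPKM in silica from 6 months on, while 1 silica library at 12 months lies at or near the air libraries in every panel.

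The number of genes called in silica against air was 113 at 1 month (108 higher and 5 lower), 233 at 3 months (203 and 30), 353 at 6 months (271 and 82), 393 at 9 months (249 and 144), 302 at 12 months (186 and 116) and 196 at 18 months (151 and 45). Without silica replicate 3 of 12 months, a library described further on, 457 genes were called at 12 months. The lower count at 12 than at 9 months therefore rests on that library. In the mean over times 736 of 1278 genes were called, 479 higher and 257 lower. The share called higher was 95.6%, 87.1%, 76.8%, 63.4%, 61.6% and 77.0% from 1 to 18 months and 65.1% in the mean. It rested on the scaling: after centring each library on its median it was 58.5%, 48.1%, 58.9%, 54.2%, 47.6% and 50.7%, and 44.1% in the mean, and after quantile normalization 61.0%, 44.5%, 46.6%, 45.8%, 43.4% and 52.3%, and 41.1% in the mean. Changes of log2 1 or more were called in 5, 15, 18, 26, 14 and 16 genes. Of the 645 genes called at 1 or more times, 41 were called higher at all 6, 36 of them with a gene symbol, including Cd177, Ceacam10, Sod2, Arg1, Enpp3, P2ry2, Oscar, C5ar1, Lpcat1, Napsa, Itgax and the signalling adaptor gene Tyrobp, and 1, Alpk3, was called lower at all 6. The 6-month and 9-month calls shared 190 higher genes, where independent lists would share 52.8, and 56 lower genes against 9.24.

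**Figure D2:**
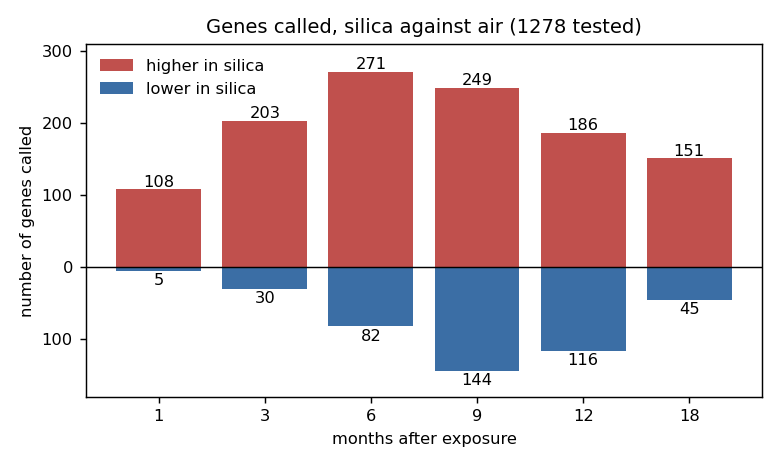
Number of genes called at adjusted p under 0.05 (vertical axis) in silica against air of the same time (horizontal axis, months after exposure), with genes higher in silica above 0 in red and lower genes below 0 in blue. Calls range from 113 at 1 month to 393 at 9 months, and the split between higher and lower changes with the scaling of the libraries.

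At 1 month after exposure Cd177 stood at 29.1 ± 0.671 (SD, n = 5) FPKM in silica and 6.69 ± 2.203 (SD, n = 5) in air, a log2 change of 2.102 ± 0.23 (SE; limma adjusted p = 6.75e-10). Every silica library lay above every air library for it and for Enpp3 (0.78 ± 0.16), Itgax, the integrin alpha X gene of macrophages and dendritic cells (0.75 ± 0.13), the ribosomal protein gene Rps16 (1.41 ± 0.39), the clock-controlled transcription factor gene Dbp (0.88 ± 0.27) and the folate receptor gene Folr1 (0.72 ± 0.24). Zfp324, a zinc finger gene, was the only named gene that fell, by 0.20 ± 0.064. Such separation held for 113 genes, against 0.794% of genes by chance. Among lists, 6 of 19 myeloid receptor genes rose, with Siglec8 at 0.51 ± 0.11 and C5ar1 at 0.67 ± 0.14 (camera adjusted p = 0.00204), as did 3 of 12 leukocyte integrin genes (0.00956), 4 of 16 lysosome genes (0.00956) and 4 of 6 alveolar type 2 related genes (0.0103). The erythrocyte list ranked lower with 0 of 3 genes called, also 0 adjusted over the list alone (median -0.38, adjusted p = 0.0228), and the zinc finger list ranked lower (adjusted p = 0.0103) although its median was -0.000438 and its mean 0.00574. These 6 lists had adjusted p = 0.399 to 0.578 with an estimated correlation. The erythrocyte and zinc finger lists also missed by exact permutation of list means (adjusted p = 0.321 and 0.875) and by the rotation test fry (0.130 and 0.989).

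Calls at 1 month depended on single libraries and on scaling. Their number was 44 without air replicate 2, 66 without silica replicate 5 and 65 after median centring. Rps16 lost its call without either of those 2 libraries (adjusted p = 0.0650 and 0.0589). Dbp lost it without air replicate 1, 2 or 5 or silica replicate 4 or 5 (0.0645 to 0.130), Folr1 without air replicates 1 to 4 or silica replicate 3, 4 or 5, each left out alone (0.0656 to 0.144), and Zfp324 without any single air replicate or silica replicate 1, 4 or 5 (0.0515 to 0.0993). Dbp and Folr1 also missed it after median centring (0.0651 and 0.0935) or quantile normalization (0.0590 and 0.0850), and with Zfp324 when no filter was set (0.0592 to 0.0813). Folr1 missed it with a pseudocount of 1 (0.0664), and Zfp324 in a fit of the 1-month groups alone (0.0596).

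At 3 months Cd177 reached 45.0 ± 4.42 (SD, n = 5) FPKM in silica against 5.33 ± 0.974 (SD, n = 5) in air, 7.86-fold on the fitted scale (log2 2.98 ± 0.23, SE; limma adjusted p = 2.60e-15). Sod2 rose from 21.9 to 56.0 FPKM (1.34 ± 0.15) and Arg1 from 4.09 to 10.6 (1.28 ± 0.18). Ceacam10 (1.38 ± 0.20), Itgax (1.06 ± 0.13) and Meis3 (1.01 ± 0.22) rose as well. Dbp fell by 1.04 ± 0.27, opposite to its change at 1 month. Adcy2, an adenylyl cyclase, fell by 0.46 ± 0.13, the insulin-like growth factor receptor gene Igf1r by 0.32 ± 0.10, and Myct1 by 0.36 ± 0.12. In these genes no silica and air library overlapped, which held for 162 genes against 0.794% by chance. Myct1 lost its call without silica replicate 1, 2 or 4 or air replicate 1, 3 or 5, each left out alone (adjusted p = 0.0512 to 0.0907), and without a filter (0.0613).

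The lysosome list rose in 11 of 16 genes at 3 months (camera adjusted p = 7.22e-06), with the organelle biogenesis gene Hps5 at 0.39 ± 0.059 (SE), and the myeloid receptor list in 10 of 19 (1.11e-04), with C5ar2 at 0.75 ± 0.11. Alveolar type 2 related genes rose in 4 of 6 (0.00285), oxidant genes in 5 of 15 (0.0267) and airway genes in 7 of 19 (0.0286). The endothelial list ranked lower with 1 of 10 genes called (0.00928), as did matrix genes with 3 lower and 3 higher of 27 (0.0338) and zinc finger genes with 2 lower and 2 higher of 48 (0.0149). Cilia genes (median -0.078, adjusted p = 0.0149) and lymphocyte genes (median -0.12, 0.0169) ranked lower with no gene called. All 10 lists had adjusted p = 0.356 to 0.425 with an estimated correlation. The matrix, zinc finger, cilia and lymphocyte lists missed by exact permutation of list means (adjusted p = 0.238 to 0.706), and these and the endothelial list by fry (0.146 to 0.586).

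At 6 months Lilrb4 stood at 32.2 ± 1.82 (SD, n = 5) FPKM in silica and 8.48 ± 1.12 (SD, n = 5) in air, a log2 change of 1.87 ± 0.19 (SE; limma adjusted p = 2.94e-10). Esr1, near its air level at the earlier times, stood at 2.50 ± 0.178 (SD, n = 5) FPKM against 0.441 ± 0.1002 (SD, n = 5) (1.68 ± 0.28, adjusted p = 6.43e-06). Cd177 (1.84 ± 0.23), Ceacam10 (1.51 ± 0.20), Plaur (1.31 ± 0.17) and Itgam (1.31 ± 0.20) rose too. Lrrc32, which holds latent TGF-beta at the cell surface, fell by 0.60 ± 0.15, Igf1r by 0.56 ± 0.10, the splicing factor gene Nova2 by 0.54 ± 0.14 and Dll1 by 0.64 ± 0.21. No silica and air library overlapped for these 10 genes, nor for 322 genes in all against 0.794% by chance. Dll1 lost its call without air replicate 2 or 4 or silica replicate 2 or 4, each left out alone (adjusted p = 0.0513 to 0.0705).

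At this time 13 of 19 myeloid receptor genes rose, including Fcar, the IgA Fc receptor gene (1.24 ± 0.16, SE), and Cd33 (1.14 ± 0.17; camera adjusted p = 6.28e-07 for the list). Lysosome genes rose in 13 of 16 (6.28e-07), alveolar type 2 related genes in 5 of 6 (9.73e-04), airway genes in 10 of 19 (0.00332), oxidant genes in 10 of 15 (0.0132) and leukocyte integrin genes in 6 of 12 (0.0464). Cell cycle genes rose in 6 of 14 (0.0132), with Mki67 at 0.86 ± 0.13 and the ribonucleotide reductase gene Rrm1 at 0.49 ± 0.081, and mitochondrial genes in 10 of 24 (0.00638), with the pyruvate carrier gene Mpc1 at 0.41 ± 0.083. The endothelial list fell in 4 of 10 genes (2.04e-04), with Ehd2 at -0.30 ± 0.065 and Rasip1 at -0.39 ± 0.11. Matrix genes fell in 7 and rose in 2 of 27 (0.0124), zinc finger genes fell in 4 and rose in 1 of 48 (0.00332), cytochrome P450 genes fell in 2 of 11 (0.0271), and cilia genes ranked lower with none called (0.0132). With an estimated correlation these 13 lists had adjusted p = 0.208 to 0.475. The cytochrome P450 and cilia lists missed by exact permutation of list means (adjusted p = 0.147 and 0.254), and these and the matrix and zinc finger lists by fry (0.0985 to 0.366).

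At 9 months Esr1 reached 5.40 ± 1.70 (SD, n = 5) FPKM in silica against 0.459 ± 0.0833 (SD, n = 4) in air, 5.95-fold on the fitted scale (log2 2.57 ± 0.29, SE; limma adjusted p = 7.31e-09). Cd177 (1.65 ± 0.24), Lilrb4 (1.61 ± 0.20), Ceacam10 (1.39 ± 0.22), Tmem86a (1.30 ± 0.23) and Enpp3 (1.28 ± 0.17) rose. Akap12 fell from 23.8 ± 0.727 (SD, n = 4) to 13.4 ± 2.27 (SD, n = 5) FPKM, a log2 change of -0.82 ± 0.13. Slc7a10 fell by 0.83 ± 0.15, Fxyd1 by 0.78 ± 0.16 and Acsm5 by 0.77 ± 0.14. For 314 genes, these 10 included, no silica and air library overlapped, against 1.59% by chance with 5 and 4 libraries.

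All 10 endothelial genes fell at 9 months (median -0.53; camera adjusted p = 4.30e-07). They included Ehd2 (-0.48 ± 0.069, SE), Rasip1 (-0.60 ± 0.12), the prostacyclin receptor gene Ptgir (-0.65 ± 0.13) and the Frizzled receptor gene Fzd4 (-0.61 ± 0.13). The mean of the list was lower in all 5 silica libraries than in the 4 air libraries (exact two-sided permutation p = 0.00794, the smallest these groups allow). Lysosome genes rose in 13 of 16 (4.62e-06), myeloid receptor genes in 12 of 19 (2.22e-04), oxidant genes in 9 of 15 with 1 lower (0.00242), alveolar type 2 related genes in 4 of 6 (0.00290) and airway genes in 10 of 19 with 1 lower (0.0273). Cell cycle genes rose in 8 of 14 (0.00263), with Mki67 at 1.11 ± 0.14 and the kinesin gene Kif22 at 0.95 ± 0.15. Matrix genes fell in 10 and rose in 5 of 27 (0.0200), with the collagen chaperone gene Serpinh1 at -0.37 ± 0.084 and the laminin gene Lama2 at -0.55 ± 0.13, while cilia genes fell in 3 of 20 (0.0200) and zinc finger genes fell in 6 and rose in 3 of 48 (0.0273). With an estimated correlation these 10 lists had adjusted p = 0.238 to 0.6003. By exact permutation of list means the airway and cilia lists missed (adjusted p = 0.133 and 0.435), and by fry the matrix, cilia and zinc finger lists (0.0517 to 0.172).

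**Figure D3:**
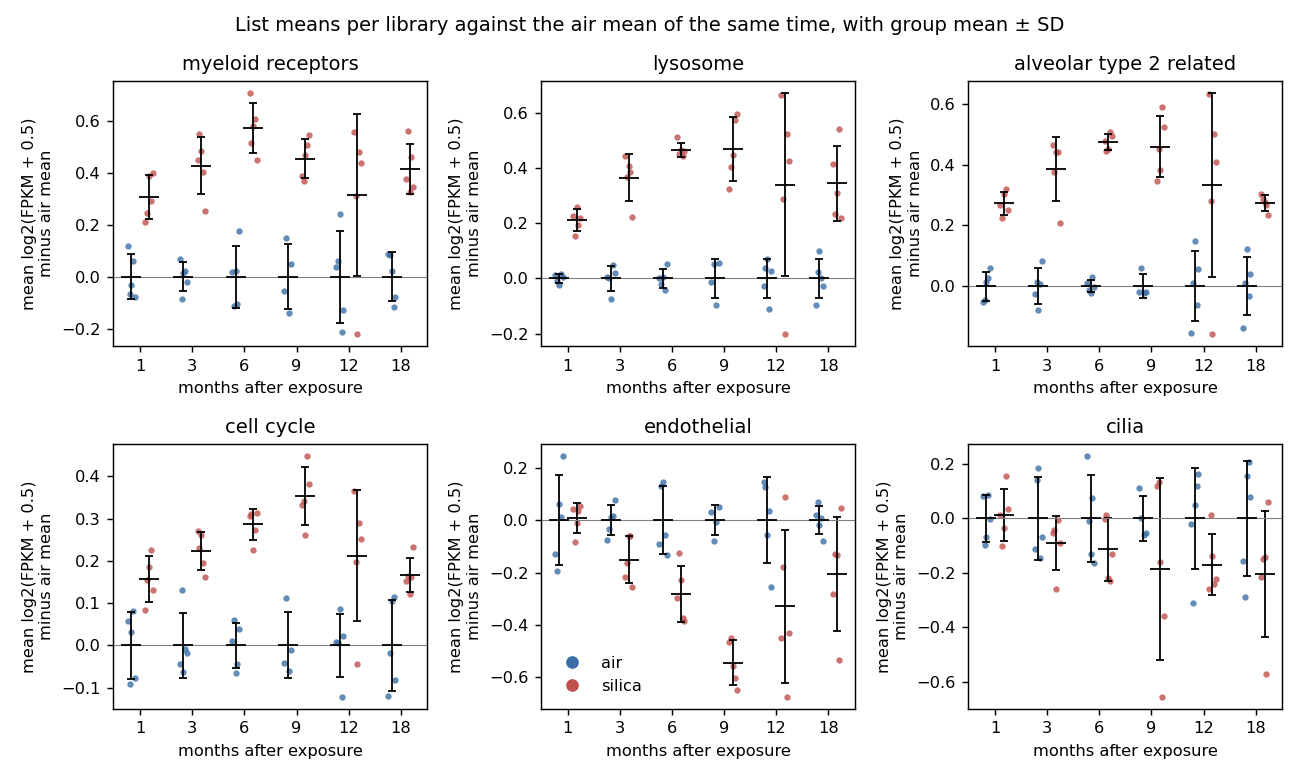
Mean log2(FPKM + 0.5) of 6 gene lists per library minus the air mean of the same time (vertical axes) against months after exposure, with air in blue, silica in red and bars for the group mean ± SD (n = 5, air at 9 months n = 4). At 9 months the endothelial mean of all 5 silica libraries lies below that of the 4 air libraries.

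At 12 months Esr1 stood at 5.30 ± 3.24 (SD, n = 5) FPKM in silica and 0.372 ± 0.0622 (SD, n = 5) in air, a log2 change of 2.40 ± 0.28 (SE; limma adjusted p = 1.98e-08). Rps16 (1.34 ± 0.39), the zinc finger gene Zfp874b (0.67 ± 0.12), the Mediator subunit gene Med25 (0.47 ± 0.13), Furin (0.41 ± 0.089) and Fbl, fibrillarin of the nucleolus (0.41 ± 0.12), rose without overlap between the groups. Nell1 fell by 0.62 ± 0.14, the hormone-sensitive lipase gene Lipe by 0.60 ± 0.10, Prkcdbp, a protein of caveolae, by 0.55 ± 0.10, and the sulfotransferase gene Ust by 0.52 ± 0.13. Groups separated fully for 43 genes, against 0.794% by chance. The library labelled silica replicate 3 lay with the air libraries: over the 59 genes raised by at least log2 0.5 at the other 5 times its mean was -0.079 from the air mean, where the other 4 silica libraries stood at 0.71 to 1.22. Without it 457 genes were called (280 higher and 177 lower), and Esr1 stood at 2.96 ± 0.18. Leaving it out of the other comparisons was chosen after its values were seen. The naming rule required every silica library, this one included, to lie beyond every air library. Larger changes that missed this, such as those of Cd177 and Lilrb4 given further on, were therefore not named at 12 months.

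Lysosome genes rose in 10 of 16 at 12 months (camera adjusted p = 2.64e-04), with Tpp1 at 0.40 ± 0.068 (SE), and the endothelial list fell in 5 of 10 (3.26e-04), with Ehd2 at -0.33 ± 0.065 and the transcription factor gene Hey2 at -0.48 ± 0.12. Myeloid receptor genes rose in 9 of 19 and fell in 1 (0.00615), with Oscar at 0.68 ± 0.13. Oxidant genes rose in 7 of 15 (0.00885), alveolar type 2 related genes in 4 of 6 (0.00885), cell cycle genes in 6 of 14 (0.0321) and airway genes in 6 of 19 (0.0321), while zinc finger genes fell in 4 and rose in 2 of 48 (0.0236) and cilia genes ranked lower with none called (0.0348). Adjusted p for these 9 lists was 0.383 to 0.604 with an estimated correlation. By exact permutation of list means none of the 9 passed (adjusted p = 0.167 to 0.231; oxidant and cell cycle genes passed unadjusted, at p = 0.0238 and 0.0397), and the unadjusted p was 0.0714 for the endothelial and 0.111 for the myeloid receptor list. Fitting the 12-month groups alone left 1 gene called. All 10 genes named at 12 months, Esr1 included, lost their calls in that fit (limma adjusted p = 0.0637 to 0.152). In the full fit the count was 195 without silica replicate 1 and 198 without silica replicate 4. Without air replicate 5 Rps16 stood at only 0.81 and Med25 at 0.33, and both lost their calls (adjusted p = 0.0922 and 0.0611).

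**Figure D4:**
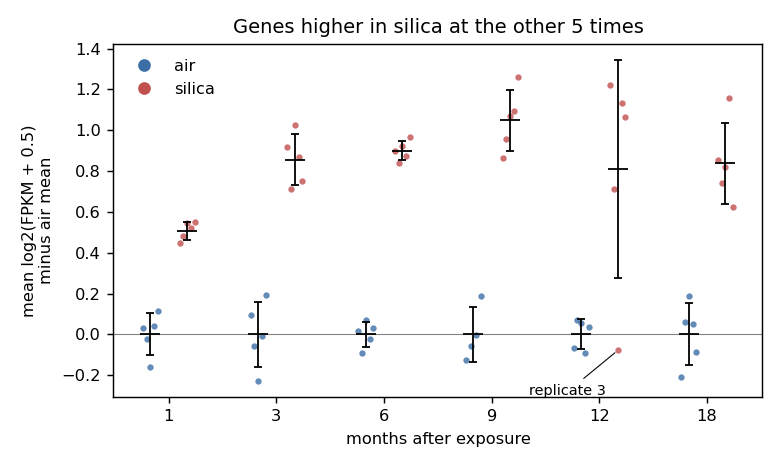
Mean log2(FPKM + 0.5) per library minus the air mean of the same time (vertical axis) over the genes higher in silica by at least log2 0.5 in the mean of the other 5 times, against months after exposure, with air in blue, silica in red and bars for the group mean ± SD (n = 5, air at 9 months n = 4). Of 30 silica libraries 29 lie above all air libraries of their time, and silica replicate 3 of 12 months lies among the air libraries.

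At 18 months Cd177 stood at 30.0 ± 5.07 (SD, n = 5) FPKM in silica and 7.28 ± 2.83 (SD, n = 5) in air, a log2 change of 2.04 ± 0.23 (SE; limma adjusted p = 1.64e-09), and Esr1 at 3.34 ± 1.05 (SD, n = 5) against 0.432 ± 0.127 (SD, n = 5) (2.01 ± 0.28). Lilrb4 (1.22 ± 0.19), Ceacam10 (1.19 ± 0.20), Sod2 (1.12 ± 0.15) and Tmem86a (1.05 ± 0.21) rose. Cd163l1, a scavenger receptor gene, fell by 0.81 ± 0.22, Acsm5 by 0.51 ± 0.13, the kinase gene Hipk4 by 0.40 ± 0.14 and Hbb by 0.55 ± 0.19. No silica and air library overlapped for these 10 genes, nor for 142 in all against 0.794% by chance. Without silica replicate 4 the count of calls was 112. After quantile normalization Hbb changed by -0.25 and was not called (adjusted p = 0.611), nor was it without a filter (0.325) or in a fit of the 18-month groups alone (0.101). It also lost its call without air replicate 1, 3 or 4 or silica replicate 3 or 4 (adjusted p = 0.0552 to 0.187) and Hipk4 lost its own without air replicate 1, 2 or 5 or silica replicate 3 or 4 (0.0769 to 0.162), each left out alone, without a filter (0.0601) or in the fit of these groups alone (0.0643).

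Myeloid receptor genes rose in 11 of 19 at 18 months (camera adjusted p = 1.36e-06), with Oscar at 0.79 ± 0.13 (SE), and lysosome genes in 9 of 16 (4.46e-06). Apolipoprotein and lipid genes rose in 6 of 16 (0.0142), with Apoe, apolipoprotein E, at 0.94 ± 0.19 and Apobr at 0.70 ± 0.12. Airway genes rose in 7 of 19 (0.0142), oxidant genes rose in 5 and fell in 1 of 15 (0.0210), and alveolar type 2 related genes rose in 3 of 6 (0.0147). Cytochrome P450 and conjugation genes fell in 3 of 11 (0.0147), with Cyp2b2 at -0.41 ± 0.12 and Cyp2e1 at -0.61 ± 0.20, and zinc finger genes fell in 4 and rose in 1 of 48 (0.00398). The cilia (median -0.26, adjusted p = 8.74e-04) and endothelial lists (median -0.19, 0.00398) ranked lower with no gene called. B cell markers ranked lower with 0 of 3 genes called, 1 adjusted over the list alone (median -0.48, adjusted p = 0.0451), as did lymphocyte genes, with 1 of 17 called higher (0.0394). Adjusted p for these 12 lists was 0.283 to 0.446 with an estimated correlation. By exact permutation of list means 9 of them missed (0.0667 to 0.481; 0.0972 for the endothelial list, unadjusted p = 0.0556), all except the myeloid receptor, lysosome and alveolar type 2 related lists.

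The size of the silica difference varied between times in 17 genes (limma F test over the 6 times, adjusted). Among genes with a symbol Esr1 had the smallest p (adjusted p = 2.87e-06), with log2 changes of -0.00301, 0.18, 1.68, 2.57, 2.40 and 2.01 from 1 to 18 months. For Lilrb4 they were 0.31, 0.70, 1.87, 1.61, 0.99 and 1.22 (adjusted p = 0.00195), and for Cd177 2.102, 2.98, 1.84, 1.65, 1.36 and 2.04 (0.0314). The clock genes Dbp and Arntl moved against each other, with 0.88, -1.04, 0.84, 1.16, 0.17 and 0.65 for Dbp (0.00291) and -0.13, 0.22, -0.33, -0.61, -0.21 and -0.37 for Arntl (0.0319). Prkcdbp ran through -0.11, -0.16, -0.26, -0.76, -0.55 and -0.18 (0.0314) and Nell1 through 0.22, -0.17, -0.52, -0.66, -0.62 and -0.39 (0.0319). Moxd1 (0.27, 0.24, -0.20, -0.16, -0.29 and 0.23; 0.0314), Inpp5a (-0.00329, -0.13, -0.22, -0.51, -0.33 and -0.23; 0.0319) and Trim3 (0.018, 0.066, -0.11, -0.32, -0.21 and -0.14; 0.0369) completed the 10 genes with the smallest p. The SE of these changes lay between 0.061 and 0.29.

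Single times carried some of these results. The count was 5 without 1 month, 3 without 3 months, 3 without 6 months and 89 without 12 months, and 78 without silica replicate 3 of 12 months alone. Esr1 kept its call whichever time was left out. Dbp (adjusted p = 0.524) and Cd177 (0.546) lost theirs without 3 months, and Lilrb4 without 1 month (0.153) or 6 months (0.0735). Cd177 also missed it without 6 months (0.0545) or 9 months (0.0503). Moxd1, Prkcdbp, Nell1, Inpp5a, Arntl and Trim3 lost their calls without 1, 3 or 6 months, each left out alone (adjusted p = 0.0545 to 0.625), and all of them except Moxd1 and Nell1 also without 9 months (0.229 to 0.331). After median centring Moxd1, Nell1, Inpp5a, Arntl and Trim3 missed the threshold (0.0610 to 0.151). Moxd1, Inpp5a and Trim3 also missed it after quantile normalization (0.0550 to 0.0898). Inpp5a, Arntl and Trim3 did so without the 2 libraries dominated by LOC102553223 (0.0518 to 0.0710).

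Between 1 and 18 months the silica difference changed significantly in 2 genes. It grew for Esr1 by 2.01 ± 0.39 on the log2 scale (SE; limma adjusted p = 0.00581) and fell for Map4k1, a kinase of haematopoietic cells, by 0.66 ± 0.15 (adjusted p = 0.0432). Map4k1 stood 0.46 from air at 1 month and -0.20 at 18 months. At an unadjusted p under 0.05 the comparison held 127 genes. B cell markers (median -0.52; 0 of 3 genes called and 1 lower adjusted over the list alone; camera adjusted p = 0.0269), lymphocyte genes (median -0.27, 1 of 17 called, 0.0207) and cilia genes (median -0.28, 0 of 20, 0.0269) ranked lower. Apolipoprotein (median 0.056, 0.0207), lysosome (0.079, 0.0207) and myeloid receptor genes (0.048, 0.0209) ranked higher with none called. With an estimated correlation these 6 lists had an adjusted p = 0.777. Map4k1 lost its call when any of 13 of the 20 libraries was left out alone, air replicate 1 or 5 or silica replicate 3, 4 or 5 of 1 month, or any air replicate or silica replicate 1, 3 or 4 of 18 months (adjusted p = 0.0611 to 0.116), and without a filter (0.0881).

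In air lungs 279 genes differed between 18 months and 1 month, 222 higher and 57 lower. Ctgf, a matricellular growth factor, rose 1.98-fold (log2 0.98 ± 0.11, SE; limma adjusted p = 1.94e-09). Rps16 rose by 2.13 ± 0.39, Cd163l1 by 1.18 ± 0.22, the cytochrome P450 genes Cyp2s1 by 0.94 ± 0.15 and Cyp2e1 by 0.85 ± 0.20, and Zfp36, an RNA-binding regulator of inflammatory transcripts, by 0.84 ± 0.16. Art2b, an ADP-ribosyltransferase gene of T cells, fell by 0.85 ± 0.20, Alpk3 by 0.54 ± 0.10, and the stress-response gene Nupr1 by 0.60 ± 0.16, with its near copy Nupr1-2 at -0.58 ± 0.16, so reads of the pair cannot be separated. No gene list passed (camera, lowest adjusted p = 0.0537, for NF-kB and TNF genes with 7 of 13 higher, although 4 lists had an unadjusted p under 0.05 and the rotation test fry called 4). Rats of these groups differed in age and in any batch of processing, and these cannot be told apart here. The share called higher was 79.6%, and 42.5% after median centring or 48.5% after quantile normalization.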

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

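The tests that weigh explanations for the clock genes and for Esr1 were chosen after the results were seen, while the test for a library far from its group, the F test between times and the comparison of 18 months with 1 month were set before.

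Esr1 differed between times (F test adjusted p = 2.87e-06) and its silica difference grew by 2.01 on the log2 scale from 1 to 18 months, higher in all silica than all air libraries at 6, 9, 12 and 18 months, though at 12 months silica replicate 3 (0.469 FPKM) stood barely above the highest air library (0.458). At 9 months the nearest tested gene on each side did not rise, Ccdc170 at -0.0076 ± 0.13 (SE) and Syne1 at -0.48 ± 0.085. The highest of the 5 tested genes on each side, Fbxo5, rose by 0.60 ± 0.13. That lay below the limit of 1.29, the midpoint between 0 and the Esr1 change. The limit cannot decide on reads from neighbouring genes, since shared reads would add FPKM rather than a log2 change. Such reads from farther or untested genes stay open. A shift of later batches in both groups is argued against by the air libraries, whose Esr1 at 6 to 18 months lay 0.079 ± 0.17 above that at 1 and 3 months. A rise in proportion to the myeloid receptor list would put the 3-month change at 2.42, and it was 0.18 ± 0.28, which argues against the same share of the same myeloid cells at both times. A change within those cells, the arrival of other cells between 3 and 6 months, and regulation within lung cells may each account for it and stay open, as untested.

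Dbp (F test adjusted p = 0.00291) and Arntl (0.0319), which oppose each other over the day in the clock of many tissues, differed between silica and air with opposite signs at 6 of 6 times, and Dbp was lower in silica at 3 months alone. A silica effect of one direction is argued against, as the 3-month Dbp difference lay -1.77 ± 0.30 (SE) from the mean of the other 5 times. The hour of tissue collection is a candidate explanation. Within groups, deviations of Dbp and Arntl from their group means correlated at r = -0.795 over 59 libraries (rho = -0.745, permutation p = 1e-05 for both, the smallest 100000 resamples can give, and r = -0.738 without the 2 libraries farthest from the median of Dbp). As the 2 genes oppose each other in the clock, such a correlation can arise whatever set the groups apart. Neither it nor the opposite signs tell the hour of collection from a silica effect on the clock. The group with the higher title numbers also had the higher Dbp at 6 of 6 times. Silica held the higher numbers at every time except 3 months, so only that time separates number order from treatment. At 12 months the Dbp difference was within its SE (0.17 ± 0.27). The labels give no hour of collection, so an hour that differed between groups and an effect of silica on the clock that changed with time both stay open.

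Other genes differed in their silica effect between times by the F test. Lilrb4 did so at an adjusted p of 0.00195. Moxd1, Cd177 and Prkcdbp stood at 0.0314, Nell1 and Inpp5a at 0.0319 and Trim3 at 0.0369. Map4k1 changed by -0.66 on the log2 scale from 1 to 18 months. Over the same interval the list medians moved by -0.52 for B cell markers, -0.27 for lymphocyte genes, -0.28 for cilia genes, 0.048 for myeloid receptors, 0.056 for apolipoproteins and 0.079 for lysosome genes. These list calls rest on the preset correlation: with an estimated one these 6 lists had an adjusted p = 0.777, and both fry tests called 0 lists.

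Single libraries stood far from their group in 8 of 150 groups of values tested, where chance alone gives about 7.5. The FPKM sum was 31740 in silica replicate 5 of 3 months, where the others lay at 14701 to 15731, and 38613 in air replicate 3 of 9 months against 13010 to 16787. It was 15913 in air replicate 1 of 3 months against 12818 to 13704, and 15899 in silica replicate 3 of 18 months against 16666 to 16905. Itgam was low in air replicate 4 of 6 months, at 2.82 FPKM against 3.40 to 3.56, and Esr1 in air replicate 2 of 9 months, at 0.334 against 0.494 to 0.508. Fbl was high in silica replicate 1 of 12 months, at 6.85 against 5.73 to 6.00, and Tmem86a in silica replicate 4 of 18 months, at 6.24 against 3.16 to 3.45.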

How the results depend on the processing

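Fits without silica replicate 3 of 12 months, except for the 12-month comparison, and without the 2 libraries dominated by LOC102553223 were chosen after seeing the data, and all others before. Of 99 named gene results, 35 kept direction and call under every alternative, and across all of them and the alternatives 1675 values were the same, 176 lost the call and 1 turned, Hbb in the mean over times at 0.062 after quantile normalization (adjusted p = 0.681; the cause was not tested). One alternative was the limit of log2 1, under which any named gene with a smaller change loses its call by construction. A mean FPKM of at least 5, which tests fewer genes, left 237 calls at 9 months, 110 at 18 months, 381 in the mean over times, 0 for 18 months against 1 month (limma) and 151 with age in air. Without a filter 1 gene was called for 18 months against 1 month. Median centring left 65 at 1 month. Array weights called 198 genes at 1 month, 536 at 6 months, 153 between times and 10 for 18 months against 1 month (the cause was not tested). With a change of at least log2 1 also required, calls were 5, 15, 18, 26, 14 and 16 from 1 to 18 months, 13 in the mean, 1 for 18 months against 1 month and 4 with age in air. Fitting the groups of a time alone, with fewer samples, left 1 call at 12 months and 130 at 18 months. The same fit gave 110 calls at 1 month, 209 at 3 months, 453 at 6 months and 330 at 9 months. Fewer samples alone therefore do not account for the loss at 12 months, and its cause was not tested. Calls between times numbered 5 without 1 month, 3 without 3 months, 3 without 6 months and 89 without 12 months. Without silica replicate 3 of 12 months they numbered 78, and the mean over times had 761. Leaving out 1 library at a time gave 44 to 136 calls at 1 month, 163 to 258 at 3 months, 292 to 349 at 6 months, 319 to 404 at 9 months, 195 to 457 at 12 months, 112 to 214 at 18 months, 1 to 2 for 18 months against 1 month and 202 to 281 with age in air. The remaining alternatives kept each count within 1.5-fold of its value.

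Gene list calls rested on the preset correlation: with one estimated per list, 0 lists passed in any comparison, and the lowest adjusted p was 0.208, at 6 months, while fry's test of direction and camera at other pseudocounts called lists in every comparison of silica with air. Of 79 list results, 0 kept their call under every alternative. Lists changing in either direction by fry numbered 1 at 1 month, 6 at 3 months and 6 at 18 months. Both fry tests called 0 lists for 18 months against 1 month. Exact permutation of list means called 0 at 12 months and 4 at 18 months. With age in air, where camera called 0 lists, both fry tests, a pseudocount of 1 and exact permutation each called 4 and median centring called 3 (the cause was not tested). The zinc finger list at 1 month turned to higher under fry (adjusted p = 0.989) and exact permutation (0.875), as these do not compare it with other genes.

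No paired analysis was possible because the labels give no replicate numbers that pair animals across groups. Depth was read only as relative depth, so no interval from counting is given. A change in a gene that reached an FPKM of 1 in fewer than 4 libraries was not detectable with the main filter.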

Other observations

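The tests on silica replicate 3 of 12 months, and the genes of the next 2 paragraphs, were chosen after their values were seen, and the splits of the libraries were set before.

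Several genes outside the lists were called higher in silica at all 6 times. In the mean over times the steroid 5-alpha-reductase gene Srd5a1 rose by 0.75 ± 0.054 on the log2 scale (SE; limma adjusted p = 5.57e-17), Cited2, a transcriptional coregulator, by 0.68 ± 0.051, and Fxyd5, a regulator of the sodium pump, by 0.69 ± 0.060. The aminopeptidase N gene Anpep rose by 0.57 ± 0.047, the glutamine transporter gene Slc1a5 by 0.49 ± 0.049 and the glycolytic aldolase gene Aldoa by 0.34 ± 0.036. Alpk3, a kinase of muscle, was the 1 gene called lower at all 6 times, by -0.34 ± 0.042 in the mean.

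Some transcripts varied widely between rats of 1 group. Apoe reached 405 ± 263 (SD, n = 5) FPKM in 18-month silica lungs, with a highest library of 840.3, against 184 ± 18.1 (SD, n = 5) in air. Tnni3, troponin I of heart muscle, ranged from 4.15 to 86.7 FPKM among 3-month silica lungs and from 2.80 to 59.7 among air lungs of that time, and the muscle creatine kinase gene Ckm from 0.646 to 20.2 and 0.308 to 11.3. Cyp2f4, of club cells, stood at 2.09 to 19.3 FPKM in 9-month silica lungs and 12.9 to 19.03 in air, a difference that missed the threshold (log2 -0.74 ± 0.40, adjusted p = 0.164).

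The library labelled silica replicate 3 of 12 months stood at -0.079 from the air mean over the 59 genes raised at the other 5 times, within the -0.11 to 0.089 of single air libraries against the rest, which is consistent with a wrong label or a rat that was not exposed. An exchange with an air library of that time is argued against, since 0 of the 5 lay nearer to the other silica libraries. Low depth was first tested by rank, and the library did have the lowest relative depth of the 10, 0.708 against 0.722 to 1.13, but that test was replaced after its result was seen by one on other silica libraries of relative depth under 0.8, which reached down to 0.474 and still stood at 0.52 or higher, above the highest air library of any time at 0.19. A rat that was exposed and responded little cannot be told apart from a wrong label, as its score was -7.63% of that of the other 4 and no other measure of exposure was at hand. Over 56 genes lower at the other times it stood at 0.023, and the other 4 silica libraries at -0.65 to -0.25.

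Each count of calls was set against 100 splits of its libraries, the real one included. Only the real split gave as many calls at 1 month (1 of 100 splits, 113 against a highest other of 58), 3 months (1, 233 against 145), 6 months (1, 353 against 70), 9 months (1, 393 against 328), 18 months (1, 196 against 134), in the mean over times (1, 736 against 124) and with age in air (1, 279 against 124). Chance is made unlikely there but not excluded, as 1 of 100 is the lowest share these splits can give. At 12 months 3 splits gave 302 or more, up to 404, and both others placed silica replicate 3 among the air libraries. Between times 2 splits gave 17 or more, up to 68. For 18 months against 1 month 4 splits gave 2 or more, up to 92. In these 2 comparisons, between times and 18 months against 1 month, the highest split called several times the real count. The splits reassigned silica and air within each time separately, so they can carry the shared silica effect into a difference between times. They therefore cannot decide whether chance gave these 2 counts. Without silica replicate 3 of 12 months the count between times was 78, and which libraries those splits moved was not examined.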
